A study of Mus musculus with 2 samples.

How the data were processed

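PPARγ, the nuclear receptor that drives fat cell differentiation, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 mouse fat depots, brown adipose tissue (BAT) and epididymal white adipose tissue (eWAT). Per the labels' protocols, the tissue came from male 129SV mice aged 8 to 10 weeks, was collected at zeitgeber time 10 h and was cross-linked with 1% formaldehyde. ChIP was done on lysates of 4 mice per tissue, and the DNA was pooled before sequencing, so there is 1 library per tissue and no measure of the spread between animals. Samples were grouped by the tissue named in the labels.

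The authors deposited 1 headerless list of regions per tissue, each named for regions specific to that tissue. Each row gives a position, a region name, a score and a strand that is plus throughout. Every region is 200 bp wide. The submitters' processing notes name Bowtie and HOMER, without versions or roles, and the genome builds mm8 and mm9. The lists do not say which of these builds their positions use. Positions are therefore printed as deposited, 1-based, in a build that is mm8 or mm9. The rule that made a region tissue-specific, the treatment of input DNA and the peak threshold are not given in the sources used here, and regions shared by both tissues are not analysed here.

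The score deposited by the authors has no stated unit. Within each list it takes values in even steps, as a read count multiplied by a single factor would. The step was fitted by least squares on the remainder and came to 0.0687 in the BAT list and 0.348 in the eWAT list. Within the rounding tolerance of 0.005, 99.9% of BAT scores and 99.8% of eWAT scores were whole multiples of the step, against 14.6% and 2.87% for values spread evenly. A score divided by its step is called a number of score steps below. If 1 step is 1 sequenced tag and both libraries were scaled to the same total, the BAT library held 5.07 times as many tags as the eWAT library. The total per library is unknown, since the scale of the score is not stated. Exact Poisson intervals on score steps assume 1 step per tag and cover counting error only. The region name joins the chromosome and a whole number, deposited by the authors without explanation. No regions of the 2 lists could be tested against each other by a count model, because each list gives a value in its own library alone.

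Several kinds of values were computed. The number of regions was compared as the share of all regions that came from the BAT list, with an exact (Clopper-Pearson) 95% binomial interval. Overlap between lists was counted with bedtools 2.31.1 at a minimum of 1 bp. The share of each list on each chromosome was compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over chromosomes and a threshold of 0.05. For clustering, regions with another region of the same list within 12.5 kb (between midpoints), called a close neighbour throughout, were counted. That count was set against 1000 random draws that kept the number of BAT and eWAT regions on each chromosome and drew them from the union of both lists. Scores were described by median and range. These tests compare the 2 deposited lists, not the tissues, and neighbouring regions are not independent. Intervals cover counting error only.

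The rule for naming regions was fixed before the data were examined. It takes the 5 highest-scoring regions of each list and the 5 clusters with the most regions, where a cluster joins neighbours within 12.5 kb. Ties in cluster size were broken by the highest score, a choice made after the clusters were seen. Alternatives fixed beforehand were chromosomes 1 to 19 and X alone, the upper part of each list by score (at or above its median), merging of regions within 1 kb or 12.5 kb, an overlap of 50% of the shorter region, widening by 500 bp, and neighbour distances of 5 and 50 kb. Alternatives chosen after seeing the data were a floor at the lowest BAT score, a floor of 10 score steps, leaving out the highest-scoring eWAT loci, the upper part of each list by score for clustering, and neighbours between 1 and 12.5 kb away.

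Assignment of regions to genes, the position of regions relative to genes, 21 gene lists and 28 sequence motifs had been planned. They were not run, because the gene table used for mouse names (GRCm38) is of another build than the deposited positions and no genome sequence was used here. No gene is therefore named for any region. The chromosome test was tested on simulated data of the same list sizes. With the odds of a BAT label multiplied by 2 on chromosome 8, that chromosome was called in 100 of 100 simulations. With BAT labels drawn at random from both lists at equal odds, any chromosome was called in at most 6 of 100. The observed odds ratio on chromosome 8 was 1.29, and odds that small were not simulated. Labels were drawn region by region, without the same-list clustering of the deposited lists. The clustering test called 2 of 20 simulations with labels placed at random and 20 of 20 with labels placed in runs. Each run gave 1 label to all regions joined within 12.5 kb, the distance of the test itself. That outcome was therefore nearly fixed, and weaker clustering was not simulated. The clustering simulations used the BAT count alone, with 100 draws each, so the eWAT count was not checked in this way. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.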

Results

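Brown adipose tissue burns fatty acids to make heat, whereas epididymal white adipose tissue stores lipid around the testis. PPARγ is required for the development of both kinds of fat cell, and the comparison asks where in the genome this receptor was bound in one depot and not in the other. The series title places the question in a study of EBF2, a transcription factor of brown adipocytes. The data are 2 lists of PPARγ-bound regions, 1 from a BAT library and 1 from an eWAT library, each made from the pooled ChIP DNA of 4 mice. With 1 library per tissue, none of the differences below has a replicate check.

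Each depot had a deposited list of many PPARγ regions named as specific to it, by a rule that is not given. The BAT-specific list held 3557 regions and the eWAT-specific list held 4711, which is 1.32 times as many. BAT-specific regions were 43.0% of the 8268 regions (exact 95% interval 42.0 to 44.1%). Each region spans 200 bp, so the lists cover 711400 bp for BAT and 942200 bp for eWAT. With both lists held to the lowest BAT score, 4494 eWAT regions were left and the BAT share was 44.2%, on the assumption that the scores of both lists share a scale. A floor of 10 score steps left 1738 eWAT regions and a BAT share of 67.2%. The eWAT step is 5.07 times the BAT step, so this floor is a higher score in the eWAT list than in the BAT list. Both floors lie at or below the lowest BAT region, so they could remove eWAT regions alone and the share could only rise.

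The lists are named as tissue-specific, so little overlap follows from how they were made. A single BAT region overlapped an eWAT region, and by 1 bp, on chromosome 7, where the BAT region (72526899 to 72527098, score 4.33) met the end of the eWAT region (72526700 to 72526899, score 2.44). When all regions were widened by 500 bp on each side, 15 BAT regions overlapped an eWAT region. A BAT region lay a median of 149 kb from the nearest eWAT region and 61.4 kb from the nearest other BAT region. An eWAT region lay a median of 235 kb from the nearest BAT region and 71.6 kb from the nearest other eWAT region.

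The strength of binding at these sites can be read only within a list, because the unit of the score is not stated. The BAT scores ran from 1.79 to 20.1 with a median of 3.57, which is 26, 293 and 52 score steps. The eWAT scores ran from 1.39 to 96.2 with a median of 2.79, which is 4, 276 and 8 score steps. Read as tags, the median eWAT region has a 95% Poisson interval of 3.45 to 15.8 tags and the median BAT region one of 38.8 to 68.2 tags. Of the eWAT regions, 2973 (63.1%) lay under 10 score steps, and 0 of the BAT regions did.

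**Figure D1:**
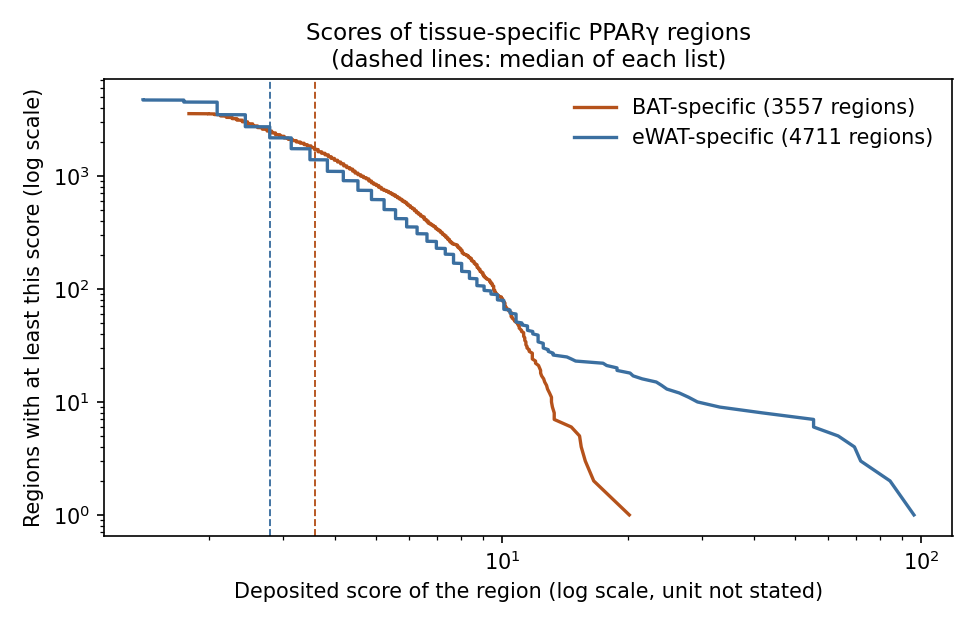
Number of regions (vertical axis, log scale) with at least a given deposited score (horizontal axis, log scale, unit not stated) in the BAT-specific and eWAT-specific lists, with dashed lines at the medians of 3.57 and 2.79. The BAT curve ends at 20.1, while 18 eWAT regions have a higher score number and reach 96.2. The scores of both lists need not share a scale.

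The 5 strongest BAT-specific sites lay on 5 different chromosomes. The highest was on chromosome 11 (116615530 to 116615729), with a score of 20.12, or 293 score steps (95% Poisson interval 260 to 329). It was followed by sites on chromosome 7 (104563056 to 104563255, score 16.55), chromosome 5 (38669585 to 38669784, score 15.8), chromosome 14 (68244354 to 68244553, score 15.45) and chromosome 2 (79209313 to 79209512, score 15.31). All positions are in the build of the deposited lists, mm8 or mm9.

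The 5 highest-scoring eWAT-specific regions fell at 2 loci, where piled-up reads could not be told apart from binding. The highest, on chromosome 9 (35112836 to 35113035), scored 96.15, or 276 score steps (95% Poisson interval 244 to 311). The next 4 lay within 4.98 kb of each other on chromosome 2, at 98507189 to 98507388 (score 84.31), 98506836 to 98507035 (score 71.76), 98502814 to 98503013 (score 69.33) and 98502406 to 98502605 (score 63.4). In all, 18 eWAT regions had a score number above that of the highest BAT region, a limit used only to pick out the top of the eWAT list, and they lay at 7 loci when regions within 50 kb were joined. Outside these loci the highest eWAT score was 18.81, reached on chromosome 13 (100507346 to 100507545) and chromosome 4 (155164273 to 155164472), 2 sites named after their values were seen.

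Both kinds of region were spread over all autosomes and chromosome X. Chromosome 2 held the largest share of both lists, with 312 BAT regions (8.77%, interval 7.86 to 9.75%) and 350 eWAT regions (7.43%, interval 6.70 to 8.22%). Chromosome 8 carried 209 BAT regions (5.88%) and 217 eWAT regions (4.61%), an odds ratio of 1.29 for BAT over eWAT. Chromosome X carried 37 BAT regions (1.04%) and 77 eWAT regions (1.63%), an odds ratio of 0.633. No chromosome passed Fisher's exact test after Benjamini-Hochberg adjustment over 21 chromosomes (smallest adjusted p = 0.190). Unadjusted p-values fell under 0.05 for 3 of them, chromosome 8 (p = 0.0104), chromosome X (p = 0.0222) and chromosome 2 (p = 0.0271), each by Fisher's exact test. Chromosome Y held 0 BAT regions and 1 eWAT region.

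**Figure D2:**
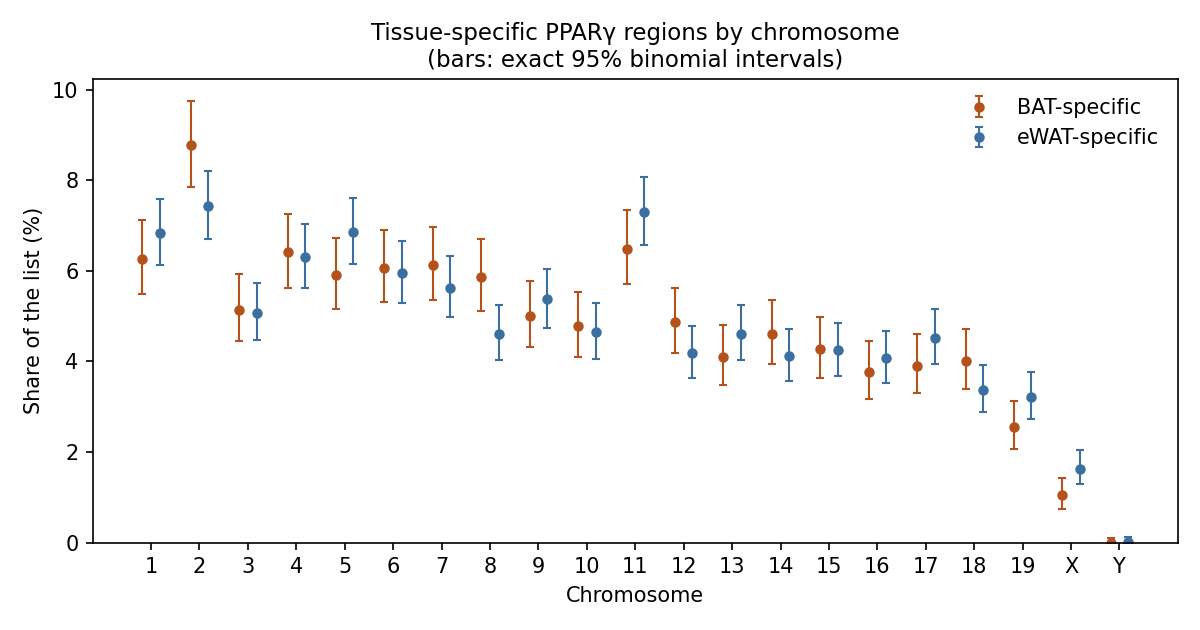
Share of each list on each chromosome (vertical axis, percent) with exact 95% binomial intervals as bars, for the BAT-specific and eWAT-specific lists. Chromosome 2 holds 8.77% of BAT and 7.43% of eWAT regions, and chromosome X holds 1.04% and 1.63%.

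Sites specific to the same depot had close neighbours of their own list more often than in random draws, though most sites had none. Of the BAT-specific regions, 850 (23.9%) had a close neighbour, that is, another BAT-specific region within the neighbour distance set for the clustering test. Random draws from the union of both lists gave a mean of 447 such regions and at most 529, so the observed number was 1.90 times the mean. Of the eWAT-specific regions, 935 (19.8%) had a close neighbour of their own list, against a mean of 746 and a highest draw of 862, a ratio of 1.25. In neither list did any of the 1000 draws reach the observed number. The ratios of the 2 lists cannot be set against each other, since the longer list has more neighbours by chance. With a floor of 10 score steps, which removes eWAT regions alone, they were 1.44 for BAT and 1.46 for eWAT. That floor makes BAT the longer list (3557 against 1738 regions), so these ratios cannot be set against each other either. In the upper part of each list by score the ratios were 1.90 for BAT and 1.36 for eWAT. By contrast, 196 BAT regions (5.51%) had an eWAT region within the same distance, and 188 eWAT regions (3.99%) had a BAT region within it.

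**Figure D3:**
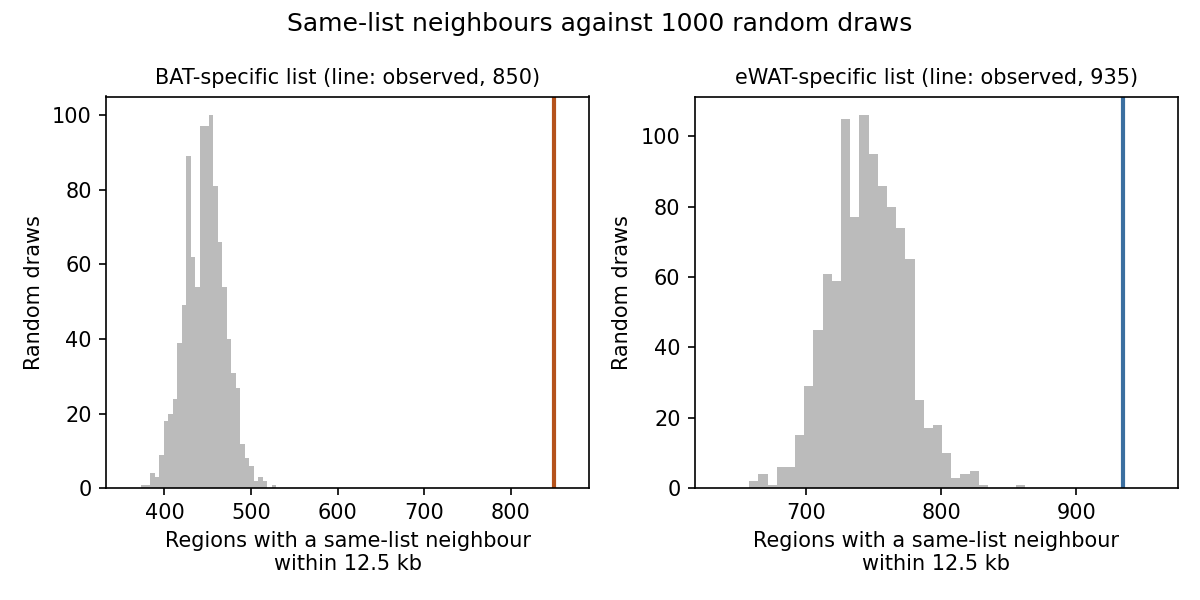
Number of regions with a close neighbour of the same list (horizontal axis) in 1000 random draws from both lists (grey bars, vertical axis: draws) and as observed (vertical line), for each list. The observed 850 BAT and 935 eWAT regions lie above the highest draws of 529 and 862.

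Most clusters were pairs: the BAT list held 318 clusters of 2 regions and the eWAT list 358. The BAT list had 48 clusters of 3, 15 of 4 and 2 of 5 regions. One cluster of 5 lay on chromosome 8 (85796451 to 85811850), where 5 BAT-specific regions with scores of 2.54 to 10.16 fell within 15.4 kb. The other cluster of 5 lay on chromosome 2 (35288142 to 35308229, scores 2.33 to 8.79). Clusters of 4 lay on chromosome 15 (85551275 to 85562458, scores 5.29 to 12.77), chromosome 5 (89346742 to 89367558, scores 2.54 to 10.44) and chromosome 9 (62353901 to 62372894, scores 3.37 to 8.72). None of these 5 clusters contained an eWAT-specific region.

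The eWAT list had 51 clusters of 3, 12 of 4, 1 of 5 and 1 of 13 regions. The cluster of 13 lay on chromosome 9 (3000012 to 3036553, scores 12.19 to 55.39), and the cluster of 5 on chromosome 2 (98502406 to 98507388, scores 55.39 to 84.31). These 2 belong to the 7 loci named above for their highest scores, and piled-up reads could not be told apart from binding there. The next clusters, of 4 regions each, lay on chromosome 4 (100347539 to 100365771, scores 2.09 to 14.63), chromosome 19 (42268036 to 42287522, scores 2.09 to 10.8) and chromosome 9 (46004992 to 46024068, scores 2.79 to 8.36). None of these 5 clusters contained a BAT-specific region. Without the 7 loci, 917 eWAT regions had a same-list neighbour, against a highest draw of 815.

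Each region's name carries a whole number that runs with the score on its chromosome (median Spearman's rho over chromosomes, across regions and not replicates, of 0.995 for BAT and 0.954 for eWAT between number and falling score) and has gaps. The highest numbers, summed over chromosomes, came to 20174 for BAT and 28413 for eWAT. The deposited regions account for 17.6% and 16.6% of these numbers. Any numbers beyond the highest deposited one on a chromosome are not counted, so these shares are upper limits. The numbers of each chromosome were divided into 10 equal bins. In bin 1, where scores are highest, 13.6% of the BAT numbers (interval 12.2 to 15.2%) and 14.1% of the eWAT numbers (interval 12.8 to 15.4%) were present. The share peaked at 24.2% in bin 4 for BAT (interval 22.3 to 26.1%) and at 21.9% in bin 3 for eWAT (interval 20.4 to 23.5%). It was 9.58% (interval 8.33 to 10.9%) and 12.1% (interval 10.9 to 13.4%) in bin 10. This count of numbers was chosen after the names were seen.

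**Figure D4:**
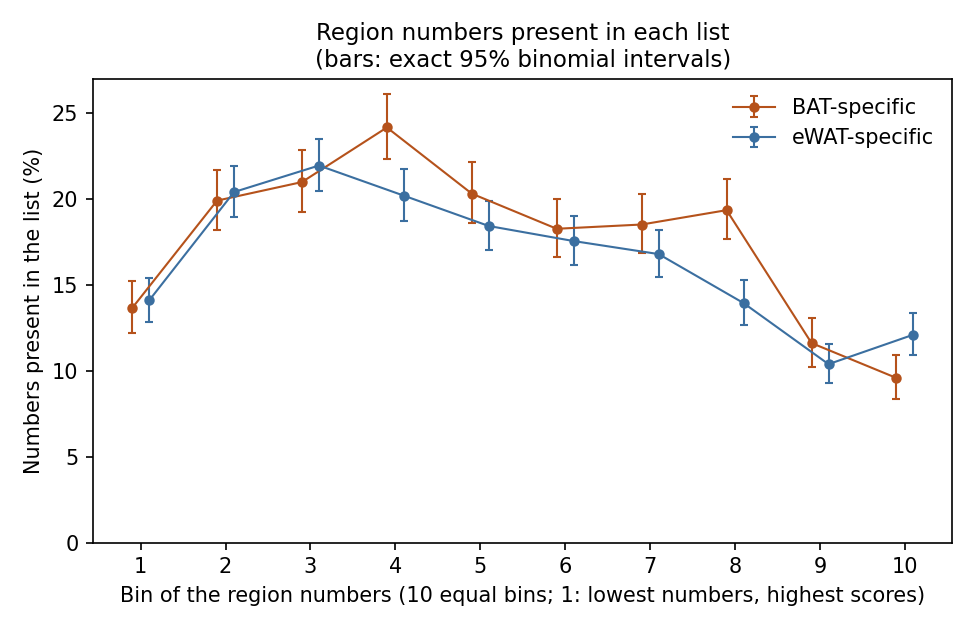
Share of region numbers present in each list (vertical axis, percent, bars: exact 95% binomial intervals) by bin of the numbers on each chromosome (horizontal axis, 10 equal bins, 1: lowest numbers and highest scores). The share is lower in bin 1 (13.6% for BAT, 14.1% for eWAT) than in the bins where it peaks (24.2% and 21.9%).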

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

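The alternatives with floors on the score, without the highest-scoring eWAT loci, with the upper part of each list for clustering and without neighbours up to 1 kb away were chosen after the data were seen. The BAT share of regions (43.0%) moved to 39.5% in the upper part of each list by score, because tied scores at the median kept 2720 eWAT and 1779 BAT regions. That setting cuts each list at its own median, so apart from ties the share could hardly move. The BAT share moved to 44.2% with both lists held to the lowest BAT score and to 67.2% with at least 10 score steps. The floor in steps is a higher score in the eWAT list than in the BAT list. Both floors remove eWAT regions alone, so the share could only rise. The 1 overlapping region became 0 when an overlap of 50% of the shorter region was required and 15 when regions were widened by 500 bp. No chromosome passed the adjusted Fisher's exact test under any of the 4 alternatives run, in which 2 or 3 chromosomes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0992 to 0.403. In all 6 alternatives for clustering the observed number exceeded every draw, with ratios of 1.44 to 2.22 for BAT and 1.10 to 1.46 for eWAT. Leaving out a library was not possible with 1 per tissue. No paired analysis was possible because each tissue has 1 library. The alternatives for gene positions, gene lists, motifs and the other build named in the notes were not run, since no gene positions or sequence of the deposited build were used. If 1 step is 1 tag, the 63.1% of eWAT regions under 10 score steps rest on fewer than 10 tags each, which limits the precision of their scores.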

Other observations

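The tests here were all chosen after the lists had been seen. That of the high-scoring eWAT loci and the floor of 10 score steps were also chosen without a bound set before their own values were known. The limits of the distance classes under 50 kb were redrawn once after the values were seen. Adjacent regions tended to come from the same list, and this tendency weakened with distance. Among regions next to each other in the union of both lists and up to 1 kb apart, 92.7% of 179 pairs came from the same list. The share was 84.1% of 439 pairs at 1 to 5 kb, 82.3% of 389 pairs at 5 to 10 kb and 70.0% of 1837 pairs at 10 to 50 kb. Draws that kept the counts per chromosome gave a mean of 51.1% at 10 to 50 kb. One hypothesis was that a preference of PPARγ for one depot extends over more than 50 kb. At 50 to 200 kb, 57.9% of 2602 pairs came from the same list (interval 56.0 to 59.8%), against a mean of 51.1% and a highest of 54.5% in 1000 draws. At 200 to 1000 kb the share was 55.7% of 2228 pairs, against a highest draw of 53.9%. These values are consistent with regional differences in PPARγ binding between the depots. Regional differences in sequencing coverage between the 2 libraries would have the same effect and were not tested.

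Same-list clustering has technical explanations that the lists bear on. If sites shared by both depots were taken out before deposit, close pairs from different lists would be missing, which could by itself raise same-list pairs at short range. With pairs up to 1 kb apart left aside, 739 BAT regions still had a close neighbour of their own list more than 1 kb away. The highest draw was 453. Removal of sites within 1 kb of each other therefore does not account for the excess beyond 1 kb. The rule that made a region tissue-specific is not given, so removal over a wider distance stays open. A few crowded eWAT loci do not account for the eWAT excess. Without them, 917 eWAT regions had a neighbour, against a highest draw of 815. A further hypothesis was that clustered sites are the stronger ones. The median score was 3.71 with and 3.43 without a close BAT neighbour, and 3.14 and 2.79 for eWAT. The medians of regions with a neighbour lay at the 99.8 percentile of 10000 random draws from the list for BAT and at the 99.9 percentile for eWAT, but the differences were small. For eWAT the medians differ by 1 score step (0.348) and the draws themselves ran from 2.79 to 3.14, so the median can take few values. For BAT the highest draw was 3.78, above the observed median.

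The highest scores of the eWAT list may come from reads piled up at a few repeated loci. The 18 eWAT regions above the highest BAT score lay at 7 loci, 38.9% of their number, whereas the 18 highest BAT regions lay at 18 loci. With lower-scoring regions within 50 kb joined to them, the 7 loci held 23 regions. The crowding came from 2 of the loci, with 5 and 13 of these regions and scores down to 12.19 in the latter. The other 5 loci held 1 region each, among them the highest score of the eWAT list (96.15). Crowding therefore says nothing about those 5, and at the 2 crowded loci it is also what a true cluster of eWAT binding would give. No sequence was examined, so repeats and binding specific to eWAT both stay open.

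The eWAT list is the longer one, and whether that is because it reaches down to weaker sites was not decided. With both lists held to the lowest BAT score, the BAT share was 44.2% (interval 43.1 to 45.3%) and the eWAT list still held 937 more regions. A floor of 10 score steps, which is a higher score in the eWAT list than in the BAT list, gave 67.2%. Both floors remove eWAT regions alone, so their direction was fixed, and the score floor assumes that both lists share a scale, which is not stated. Weaker sites, unequal depth of the libraries, a different background and a true difference between the depots stay open, since each tissue has 1 library.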
